A study of Oryza sativa with 200 samples.

How the data were processed

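Leaf RNA of 100 rice lines was sequenced in 2 years, 2022 and 2023. The lines belong to JAM2, a multi-parent population (MAGIC, a design in which several parents are intercrossed and inbred) from the varieties Akidawara, Iwaidawara, Tachiharuka and Toyomeki. Per the labels, each line was grown as 33 plants in 1 unreplicated plot with chemical fertilizer at 56 kg of nitrogen per ha. A fully expanded leaf was taken between 9:00 and 11:00, 6 weeks after transplanting, on 1 July in 2022 (generation F5) and on 29 June in 2023 (generation F6). Poly(A) RNA was turned into stranded libraries with the NEBNext Ultra II Directional kit, per the labels, and each line gave 1 library per year.

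The deposited tables hold raw counts per gene for each library, 1 table per year, with 37849 gene identifiers of the Rice Annotation Project form. The table's name, as the labels give it, says that unique exon reads were counted. The genome build was IRGSP-1.0, per the submitters' processing notes. The aligner and the counting tool are not given in the sources used here. No other normalization was applied to the deposited counts, which are whole numbers with a different total in each library. All 200 columns matched a labelled sample, 0 columns had no sample, and 0 pairs of libraries were identical. Groups were the years, with 100 libraries each, and the line number tied the libraries of a line to each other.

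No genome came with the tables. Gene names came from pairs of symbol and locus written down beforehand, from general knowledge of rice genes, for 13 gene lists. The RefSeq gene table of assembly ASM3414082v1 holds no identifiers of the deposited kind, so a pair was kept only where that table lists the symbol on the chromosome that the locus names, in a compatible order along it. Of 156 pairs, 101 were kept, 50 had a symbol that the table does not list, 3 lay on another chromosome and 2 were out of order. A kept name was therefore not contradicted by the table, but it was not matched by identifier, and each name is printed with its locus. A further 10 lists defined by keywords could not be matched, so a test of resistance genes among on/off genes and a test of heat shock genes between the years were not run. Genes without a name are given by identifier.

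The years were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on all 200 libraries, with filterByExpr by year, TMM factors and year as the sole term. A gene was called at a Benjamini-Hochberg (BH) adjusted p under 0.05 and a change of at least 2-fold. The SE of a change was derived from this fit, as the absolute log2 change divided by the square root of F, and so does not use the pairing of lines. The line numbers pair the libraries by design, since a number is the same line in both years, and all 100 lines found their own library in the other year by the genes described as on/off. The fit with the line number as a replicate block was run as an alternative, and its value is given beside a gene only where it changes the call. DESeq2 1.42.0 was another alternative. Gene lists were compared between the years with camera in limma 3.58.1 at a preset correlation of 0.01, BH adjusted over 13 lists. Of 3 lists passing, those for nitrogen and for sucrose and starch hold with an estimated correlation and that for the circadian clock does not. Calls "adjusted over the list alone" are given beside those over all genes.

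Repeatability of a gene was the Pearson r of its log2 CPM (TMM factors, prior count 2) between the years over the 100 lines, for genes with a mean of at least 1 CPM. A gene was called repeatable at r above 0 and a BH adjusted p under 0.05, from the t distribution of r. The same count was made for 100 random pairings of the lines. Named genes and pairs of genes also have Spearman's rho and two-sided permutation p-values from 100000 permutations, of which 1e-05 is the smallest possible, and an r without the 2 lines farthest from the median. For relations with line number these were the 2 lines whose numbers lay farthest from the median number, not lines with outlying expression. Where lines fell into separate clusters in both years (a gap of at least 8% of the range, a limit set after the values were seen), no pooled r is given. The median r of each list was set against 10000 random lists of the same size matched on mean log2 CPM in 20 bins.

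An on/off gene had, within a year, at least 10 lines under 0.2 CPM, at least 10 lines at 2 CPM or more and at most 10 lines between. To match libraries, each 2022 library was correlated with all 2023 libraries over the genes that were on/off in either year. Of 13 planned pairs of flowering genes 5 were run and 2 are given. The results of 1 named gene are not reported here, and the BH adjustments still count its tests. Pairs with Ehd1 were left out because its symbol was not kept, and Hd1 (Os06g0275000) had 0 counts in all 200 libraries, so its pair could not be computed. Linkage used the numbers within the gene identifiers, which follow the order along a chromosome, with 20000 numbers in place of a planned window in bases. Since windows of a chromosome are linked, the excess of windows with a share near 25, 50 or 75% was also tested by flipping its sign over 12 chromosomes, a test added after the data were seen.

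The named genes followed a rule: the genes with the most extreme change or r that have a name, a mean of at least 10 CPM and, for the years, the same sign in at least 95 lines, plus for each list the pair of members with the largest change or r, plus the flowering regulators. The other members of the 3 lists that passed are named too, a choice made after their values were seen, and WRKY62 was left out as the tandem neighbour of WRKY76. The lists, tests, thresholds, naming rule and most alternatives were chosen before the data were examined. The alternatives changed the normalization, the filters, the threshold, the prior count, the measure, the lines or libraries kept and the depth. Added after the data were seen were the split by the depth of the 2022 library and the removal of a trend over column position in the tables.

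The year comparison and the repeatability step were tested on simulated data, and the other steps were not. With counts drawn from the real means and library sizes, the year comparison over 18521 genes recovered 94 of 98 genes changed 1.5-fold at the adjusted p alone and 96 of 96 changed 2.5-fold at the full threshold, with 1 unchanged gene called at the full threshold and 5 at the adjusted p alone. These counts were drawn independently for each gene and library, with no line effect shared by the years and no trend over the columns. The recovery and the false calls of the year comparison may therefore not carry over to the real data. The repeatability step over 18490 genes recovered 136 of 200 genes given a line SD of 0.3 on the log2 scale and called 2 others. Line statistics and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

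A library held 3254834 to 37774023 counts in 2022 and 3729294 to 16881699 in 2023, so a gene at 1 CPM had about 3 counts in the shallowest library. The counts were of reads without molecular identifiers, so they are not independent molecules. Reads of near-identical gene copies were subject to the authors' counting of unique reads, and genes in such families are uncertain.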

Results

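The population was sampled to read gene activity in the leaves of lines that carry different mixtures of 4 parental genomes. There were 100 lines and 200 libraries, 100 in each of 2022 and 2023, with 1 leaf per line and year and no replicate plots. Library totals had a median of 7768777 counts in 2022 (range 3254834 to 37774023) and 11272411 in 2023 (range 3729294 to 16881699). In 2022 the totals were uneven, and the lines of the 30 deepest libraries were also examined apart. A library detected 21368 to 26982 genes with at least 1 count in 2022 and 21696 to 25597 in 2023. The 10 most abundant genes took 9.82% to 15.4% of a library's counts in 2022 and 12.1% to 17.3% in 2023. Gene identifiers are loci of build IRGSP-1.0, and in each the digits after Os give the chromosome.

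The first comparison asked which leaf transcripts differed between the 2 years over the same lines. Genes of nitrogen uptake and assimilation were higher in 2023 in all 7 tested members. Of the planned list 10 members had a kept name, 7 had a symbol that the reference does not list and 2 were out of order, so part of the pathway was not tested. GS1;2 (Os03g0223400), a cytosolic glutamine synthetase that fixes ammonium, rose from a mean of 27.0 ± 7.71 CPM (SD, n = 100) to 87.7 ± 22.7 CPM and was higher in 2023 in 100 of 100 lines (log2 change 1.69, SE 0.0571, adjusted p = 2.28e-72 by edgeR's quasi-likelihood test with BH adjustment). The nitrate transporter gene NRT2.3 (Os01g0704100) rose by 0.73 on the log2 scale, the nitrate reductase gene NIA1 (Os08g0468100) by 0.61 and the ammonium transporter gene AMT1;1 (Os04g0509600) by 0.48. NRT2.3 was low, with a mean of 1.26 CPM in 2022 and 2.13 CPM in 2023, and was higher in 2023 in 77 of 100 lines. Abundant enzymes of the same pathway rose less, with 0.31 for the plastid glutamine synthetase GS2 (Os04g0659100) and 0.18 each for GS1;1 (Os02g0735200) and the glutamate synthase Fd-GOGAT (Os07g0658400). As a list these genes moved up against all others (camera, adjusted p = 0.000118, and adjusted p = 0.0222 with an estimated correlation). Among the 30 lines with the deepest 2022 libraries the change of NIA1 was 0.17 (adjusted p = 0.0715) and that of GS1;1 was −0.0176 (adjusted p = 0.773), both by edgeR with BH adjustment. In 2022 the level of GS1;2 also followed the order of the columns in the table (r = 0.642 over 100 lines).

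Transcripts of 2 sucrose transporter genes were higher in 2023 as well. SUT1 (Os03g0170900), a sucrose transporter that loads sugar for export, went from 71.2 ± 15.1 CPM to 129 ± 20.1 CPM (SD, n = 100 lines), a log2 change of 0.85 (SE 0.0385) seen in 100 of 100 lines. The change of SUT2 (Os12g0641400), a sucrose transporter of the vacuole membrane, was 0.60 (SE 0.0246), also in 100 of 100 lines. The third tested member, the starch synthase gene WX (Os06g0133000), did not pass at −0.04 (adjusted p = 0.749 by edgeR with BH adjustment). WX was low, with a mean of 1.25 CPM in 2022 and 1.23 CPM in 2023. The sucrose and starch list of 3 genes passed by camera with an adjusted p of 0.00621, and of 0.0242 with an estimated correlation. Of its planned members 5 had a kept name, 2 had a symbol that the reference does not list and 1 lay on another chromosome.

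Of 7 tested genes of the circadian clock, 5 were higher in 2023 and 2 did not pass. Another 7 planned clock genes had a symbol that was not kept and were not tested. OsLHY (Os08g0157600), a transcription factor of the morning part of the clock, had a mean of 879 CPM in 2022 and 1743 CPM in 2023 (n = 100 lines), with an SD between lines of 0.67 and 0.28 on the log2 scale. Its log2 change was 0.99 (SE 0.0710, adjusted p = 6.89e-30 by edgeR with BH adjustment), with 98 of 100 lines higher in 2023. OsPRR95 (Os09g0532400), a pseudo-response regulator of the clock, rose by 0.62 in 100 of 100 lines, OsPRR73 (Os03g0284100) by 0.29 in 94 lines and OsPRR37 (Os07g0695100) by 0.20 in 87 lines. OsGI (Os01g0182600), the rice GIGANTEA gene, rose by 0.09 in 69 lines, and its call was lost by total counts (−0.0236), in the 50 lines with the higher numbers (0.0352) and in the 70 lines with shallower 2022 libraries (0.0496). OsELF3-1 (Os06g0142600) at −0.04 and OsPRR1 (Os02g0618200) at 0.03 did not pass. OsELF3-1 passed as lower in 2023 by total counts (−0.15), in the 50 lines with the lower numbers (−0.0860), with thinned libraries (−0.0502) and in the 30 lines with the deepest 2022 libraries (−0.0903). The list passed by camera (adjusted p = 0.00583), and the call was lost with an estimated correlation (adjusted p = 0.0773).

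Of the 7 clock genes, 5 followed the column order of the 2022 table and 0 that of the 2023 table at an adjusted p under 0.05 over 14 relations. In 2022 OsLHY rose with column position (r = 0.964, rho = 0.968, permutation p = 1e-05 for each, the smallest possible, adjusted p = 4.67e-05, r = 0.964 without the 2 farthest lines) and OsGI fell (r = −0.652, rho = −0.705, both permutation p = 1e-05, r = −0.631 without the 2 farthest lines). For OsLHY r was 0.881 in the 30 lines with the deepest 2022 libraries and 0.945 in the other 70. In 2023 the r of OsLHY with position was 0.0281 (permutation p = 0.782) over all columns, −0.766 in columns 1 to 50 and 0.0512 in columns 51 to 100, and that of OsGI was 0.183 (permutation p = 0.0678), 0.456 and 0.128. The change of OsLHY between the years was 0.45 in the 30 lines with the deepest 2022 libraries and 1.30 in the other 70.

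**Figure D1:**
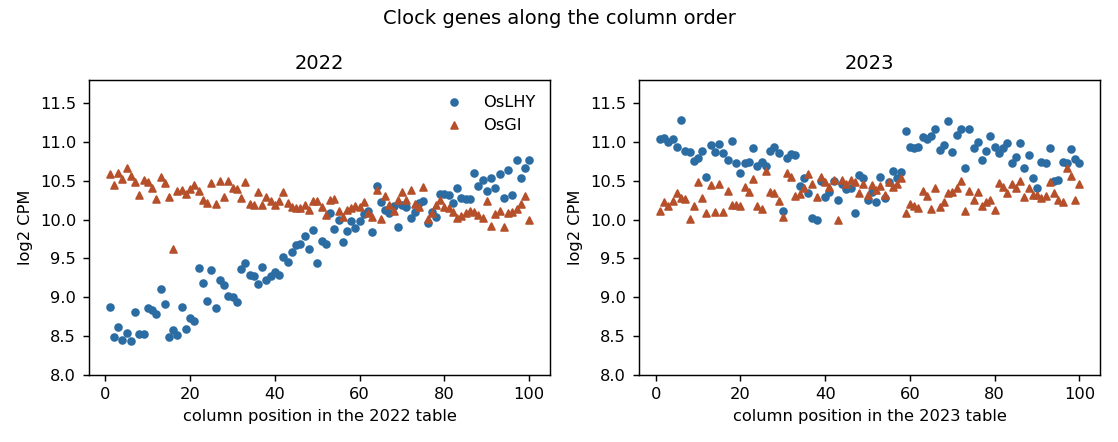
Each point is 1 line, with its position among the 100 columns of a year's table on the x axis and the log2 CPM of OsLHY (circles) or OsGI (triangles) on the y axis, for 2022 on the left and 2023 on the right. In 2022 OsLHY climbs with position (r = 0.964) while OsGI declines (r = −0.652).

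Flowering regulators went both ways between the years, with 7 of 17 higher in 2023, 5 higher in 2022 and 5 not passing. At the same adjusted p 13298 of all 18674 tested genes passed, so this count and those of the other lists have to be read against that share. Hd3a (Os06g0157700), a florigen made in leaves under short days, fell from 8.82 ± 14.7 CPM to 2.64 ± 5.70 CPM (SD, n = 100 lines), a log2 change of −1.82 (SE 0.347, adjusted p = 9.97e-07 by edgeR with BH adjustment). Lines with 0 counts of Hd3a in both years have no direction, so its lines are not counted by direction. The phytochrome genes PHYA (Os03g0719800) and PHYC (Os03g0752100) fell by 0.36 and 0.21 on the log2 scale, and PHYB (Os03g0309200) at −0.03 did not pass. The 30 lines with the deepest 2022 libraries gave 0.10 for PHYC (adjusted p = 0.0135) and 0.31 for PHYB (adjusted p = 2.06e-05), while the other 70 gave −0.18 for PHYB (adjusted p = 0.000284), all by edgeR with BH adjustment. In the 50 lines with the lower numbers PHYC was at −0.0249 and did not pass. Ehd3 (Os08g0105000) and Hd16 (Os03g0793500) changed by −0.24 and −0.10. Ehd3 was at −0.0899 (adjusted p = 0.0825) in the 30 lines with the deepest 2022 libraries and Hd16 at −0.0328 (adjusted p = 0.269) in the 50 lines with the higher numbers, both by edgeR with BH adjustment. Higher in 2023 were OsMADS56 (Os10g0536100, 0.42, in 99 of 100 lines), DTH8 (Os08g0174500, 0.34), SE5 (Os06g0603000, 0.31), OsMADS50 (Os03g0122600, 0.26) and Ehd4 (Os03g0112700, 0.14). DTH8 was at 0.14 (adjusted p = 0.161) in the 50 lines with the higher numbers and at 0.15 (adjusted p = 0.0842, both by edgeR with BH adjustment) in the 70 lines with shallower 2022 libraries. SE5 and OsMADS50 were at 0.0942 (adjusted p = 0.0927) and 0.14 (adjusted p = 0.221) in the 30 lines with the deepest 2022 libraries, and Ehd4 was at 0.0352 (adjusted p = 0.225) by total counts, all by edgeR with BH adjustment. OsMADS14 (Os03g0752800) at −0.51 did not pass. OsMADS18 (Os07g0605200) did not pass at 0.04 (adjusted p = 0.778), while with the line as a block it passed at 0.08 (adjusted p = 0.0239, both by edgeR with BH adjustment), with 61 lines higher in 2023. The flowering list as a whole did not pass by camera (adjusted p = 0.685).

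The other lists did not pass by camera, with adjusted p from 0.211 to 0.983. In the senescence and chlorophyll breakdown list 2 of 4 genes were lower in 2023. They were RCCR1 (Os10g0389200), a reductase of chlorophyll breakdown, at −1.31 (SE 0.0650, 97 of 100 lines) and NOL (Os03g0654600) at −0.30. Of 8 defence and phytoalexin genes, 5 were lower in 2023, 2 were higher and 1 did not pass. The defence transcription factor gene WRKY76 (Os09g0417600) went from 28.3 to 12.6 CPM (log2 change −1.17, SE 0.0999, 89 of 100 lines), whereas the pathogenesis-related gene PBZ1 (Os12g0555500) rose by 0.31. Of 9 dehydration, cold and abscisic acid genes 3 were higher in 2023 and 4 were lower. SALT (Os01g0348900), a lectin gene that responds to salt, rose by 1.08 (SE 0.263, adjusted p = 0.000117 by edgeR with BH adjustment, 81 of 100 lines), and NCED3 (Os03g0645900), of abscisic acid synthesis, fell by 0.47 on the log2 scale, and by 0.16 (adjusted p = 0.211 by edgeR with BH adjustment) in the 50 lines with the higher numbers. In the yield and plant type list 4 of 6 genes were higher, among them the cytokinin oxidase gene CKX2 (Os01g0197700) at 0.58. CKX2 was low, with a mean of 1.11 CPM in 2022 and 1.68 CPM in 2023, and was higher in 2023 in 60 of 100 lines. The semidwarf gene SD1 (Os01g0883800), a gibberellin oxidase, changed by −0.85 (SE 0.110, 81 of 100 lines). In the 30 lines with the deepest 2022 libraries NOL (−0.0813, adjusted p = 0.340), SALT (1.19, adjusted p = 0.0510) and CKX2 (0.26, adjusted p = 0.396) did not pass by edgeR with BH adjustment, nor did CKX2 in the 50 lines with the lower numbers (0.32).

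Nutrient and tissue lists were short. Phosphate starvation genes split, with 2 of 4 higher in 2023, among them SPX1 (Os06g0603600) at 0.30, and 1 lower, the phosphate transporter gene PT8 (Os10g0444700) at −0.31. PT8 did not pass in the 30 lines with the deepest 2022 libraries (−0.17, adjusted p = 0.104 by edgeR with BH adjustment). Both tested iron deficiency genes were higher, NAS3 (Os07g0689600) at 0.16 and IRO3 (Os03g0379300) at 0.14, and IRO3 was at −0.0258 in the 30 lines with the deepest 2022 libraries. NAS3 was at −0.0203 among the 50 lines with the higher numbers, and neither passed by total counts (0.0460 for NAS3 and 0.0337 for IRO3). The 1 tested root marker, the silicon transporter gene LSI1 (Os02g0745100), rose by 0.33. Of the markers of dividing tissue, 1 was tested, the replication factor gene PCNA (Os02g0805200), which changed by −0.34, and by −0.28 in the 30 lines with the deepest 2022 libraries (adjusted p = 0.114 by edgeR with BH adjustment). The 1 tested panicle and flower marker, OsMADS1 (Os03g0215400), did not pass at −0.33.

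Over all 18674 tested genes, 13298 differed at an adjusted p under 0.05, and of those with a change of at least 2-fold 131 were higher in 2023 and 157 higher in 2022 (edgeR's quasi-likelihood test with BH adjustment). Of these calls 45.5% were higher in 2023, and 28.3% were with libraries scaled by total counts, which moved the median change of all genes to −0.12. Of 67 list members tested, 33 were higher in 2023 and 19 in 2022, at the adjusted p over all genes. With p-values adjusted over the list alone the numbers of genes passing were 12 for flowering, 5 for the clock, 7 for nitrogen, 2 for sucrose and starch, 7 for defence, 7 for dehydration, 5 for yield, 3 for phosphate, 2 for iron, 2 for senescence, 1 for dividing tissue, 1 for root and 0 for panicle. Among genes without a name, Os04g0352400 fell from 99.7 to 7.10 CPM (log2 change −3.80, SE 0.10) and Os03g0701100 from 19.4 to 2.80 CPM (−2.79, SE 0.0861), each in 100 of 100 lines. Os06g0141200 rose from 16.2 to 91.8 CPM (2.48, SE 0.160, 99 lines) and Os08g0355400 from 13.7 to 40.7 CPM (1.56, SE 0.0822, 97 lines). Each year was 1 season, 1 sampling day and 1 generation with libraries of its own, which cannot be told apart. The time of collection within the morning was not given for single libraries, so it may also have differed between the years. Of 18490 genes, 9739 followed column position in 2022, OsLHY and OsGI among them, and 1655 did in 2023. The changes between the years were not tested with this trend removed, so they may include it. The labels give no batch of the libraries. All 30 deeper libraries of 2022 were among the 40 in the later of 2 runs of sample records, so whether 2022 held more than 1 batch stays open. The p-values measure the spread between lines within these years. Among the 50 lines with the higher numbers 544 genes were called, and with all libraries thinned to the smallest total 180 were.

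**Figure D2:**
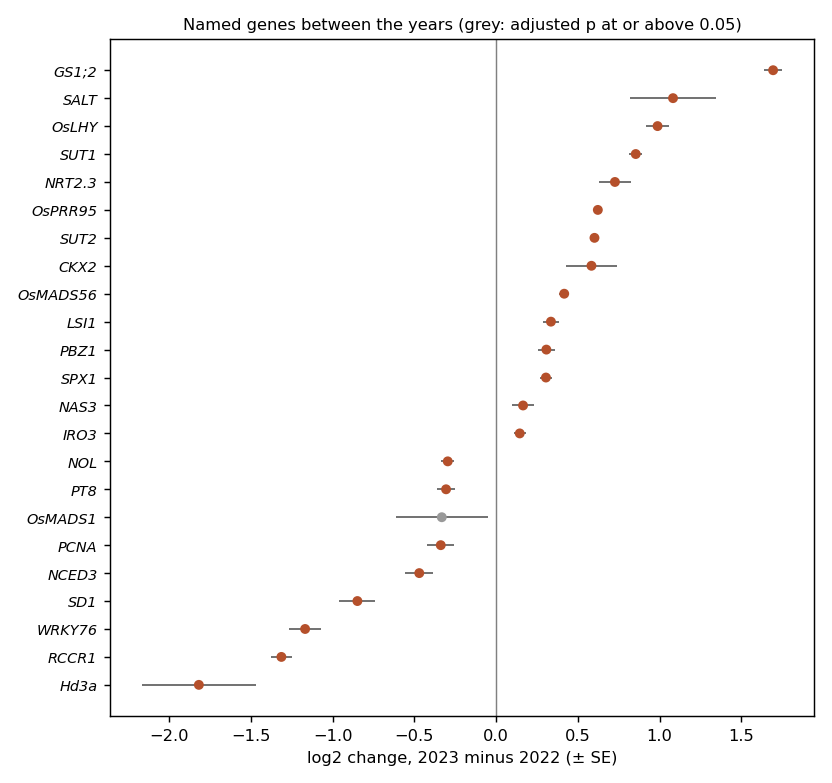
The log2 change from 2022 to 2023 is on the x axis for named genes on the y axis, with grey points for genes that did not pass. Bars are 1 SE, derived from the F statistic of edgeR's unpaired fit to 100 lines per year. GS1;2 (1.69) lies at the upper end and Hd3a (−1.82) at the lower end.

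The second comparison asked which differences between lines were seen in both years. Several flowering genes had a high r. The MADS-box genes OsMADS18 (r = 0.908, rho = 0.897), OsMADS14 (r = 0.876, rho = 0.850) and OsMADS50 (r = 0.816, rho = 0.795), and the florigen gene Hd3a (r = 0.895, rho = 0.888), were among them. The flower marker OsMADS1, at a mean of 4.90 CPM in these leaves, had r = 0.882 (rho = 0.868), and OsMADS56 had r = 0.638 (rho = 0.623). For these 6 genes each permutation p was 1e-05, the smallest possible (adjusted p = 2.73e-05 over the 41 genes tested), and without the 2 farthest lines r was 0.899, 0.869, 0.781, 0.888, 0.882 and 0.624 in the order named. Hd3a had 0 counts in 24 lines in 2022 and 33 in 2023, and OsMADS14 in 26 and 20. The r of these genes therefore also reflects whether a line read the gene at all. The flowering regulators PHYA, PHYB, PHYC, Ehd3, Ehd4, SE5 and DTH8 did not pass as repeatable by either adjustment. Hd16 (r = 0.237, rho = 0.219, permutation p = 0.0176 and 0.0293, 0.238 without the 2 farthest lines) passed over the 41 genes tested (adjusted p = 0.0249) and did not pass over all genes (adjusted p = 0.0711). The 41 genes were chosen in part for a high r in these same data, so the adjustment over them is too lenient.

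These genes also followed the column order of the tables, in which line numbers ran in opposite directions in the years (r of column position between the years −0.788). The r of OsMADS14 with position was 0.730 in 2022 and −0.838 in 2023 (rho = 0.734 and −0.831, permutation p = 1e-05 each, 0.765 and −0.831 without the 2 columns farthest from the middle). With a linear and quadratic trend over position removed in each year, r between the years was 0.367 for Hd3a, 0.352 for OsMADS1, 0.215 for OsMADS14 (adjusted p = 0.0989), 0.731 for OsMADS18, 0.672 for OsMADS50 and 0.624 for OsMADS56. In the 30 lines with the deepest 2022 libraries r was 0.665 for Hd3a and 0.922 for OsMADS18, and in the other 70 it was 0.877 and 0.886.

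Genes outside flowering repeated too. The clock gene OsPRR1 split the lines into separate groups, with 73 lines high in 2022 and 75 in 2023 and 98 of 100 on the same side. Its mean was 52.4 ± 10.4 CPM in the high and 19.1 ± 4.75 CPM in the low lines in 2022 (SD), and 53.8 ± 12.7 and 15.5 ± 4.41 CPM in 2023. Within the 73 lines high in both years r was 0.389 (rho = 0.346, permutation p = 0.00057 and 0.00292), and within the 25 low lines it was −0.309 (rho = −0.257, permutation p = 0.132 and 0.212). SALT had r = 0.766 (rho = 0.573), PCNA 0.732 (rho = 0.734), the phosphate transporter gene PT4 (Os04g0186400) 0.561 (rho = 0.562), the grain width gene GW2 (Os02g0244100) 0.531 (rho = 0.505), SUT1 0.504 (rho = 0.478) and PT8 0.454 (rho = 0.429). All of these had permutation p = 1e-05 for r and rho, and without the 2 farthest lines r was 0.746, 0.735, 0.547, 0.532, 0.434 and 0.401 in the order named. For PT8 r was 0.305 in the 30 lines with the deepest 2022 libraries, which did not pass (adjusted p = 0.302). NAS3 had r = 0.417 (rho = 0.418, permutation p = 3e-05 each) and SPX1 0.414 (rho = 0.395, permutation p = 2e-05 and 0.00013), and 0.424 and 0.382 without the 2 farthest lines. In the 30 lines with the deepest 2022 libraries SPX1 had 0.460, which did not pass (adjusted p = 0.0651). At the other end, OsLHY had r = 0.0423 (rho = 0.0928, permutation p = 0.675 and 0.360, 0.0121 without the 2 farthest lines), although in the 30 lines with the deepest 2022 libraries it was 0.501 (adjusted p = 0.0365). In those 30 lines OsLHY also followed column position in 2022 (r = 0.881), so the order of the columns may raise this value. PHYB had r = −0.0796 (rho = −0.129, permutation p = 0.431 and 0.198, −0.0877 without the 2 farthest lines).

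Of 18490 genes with a mean of at least 1 CPM, 4111 were repeatable at an adjusted p under 0.05 and 44 had a negative r past that threshold. An r of at least 0.5 was reached by 1426 genes and of at least 0.8 by 609, and the median r was 0.114 (quartiles 0.0198 and 0.233). In 100 random pairings of the lines at most 3 genes passed as repeatable. By list, the numbers of repeatable genes were 7 of 17 for flowering, 4 of 7 for the clock, 3 of 4 for phosphate, 3 of 8 for defence, 2 of 9 for dehydration, 2 of 6 for yield, 1 of 2 for iron, 1 of 4 for senescence, 1 of 3 for sucrose and starch and 1 of 7 for nitrogen. Adjusted over the list alone these were 9, 5, 4, 3, 2, 2, 1, 1, 1 and 1. None of the 10 lists had a median r outside that of matched random lists after BH adjustment (0 of 10), and 1 did at an unadjusted p, phosphate starvation (median r 0.434 against 0.119 in random lists, p = 0.0242, adjusted p = 0.242). The flowering list had a median r of 0.237 against 0.137 (p = 0.0602, adjusted p = 0.301). Each line stood in 1 plot per year, so line and plot cannot be told apart within a year.

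**Figure D3:**
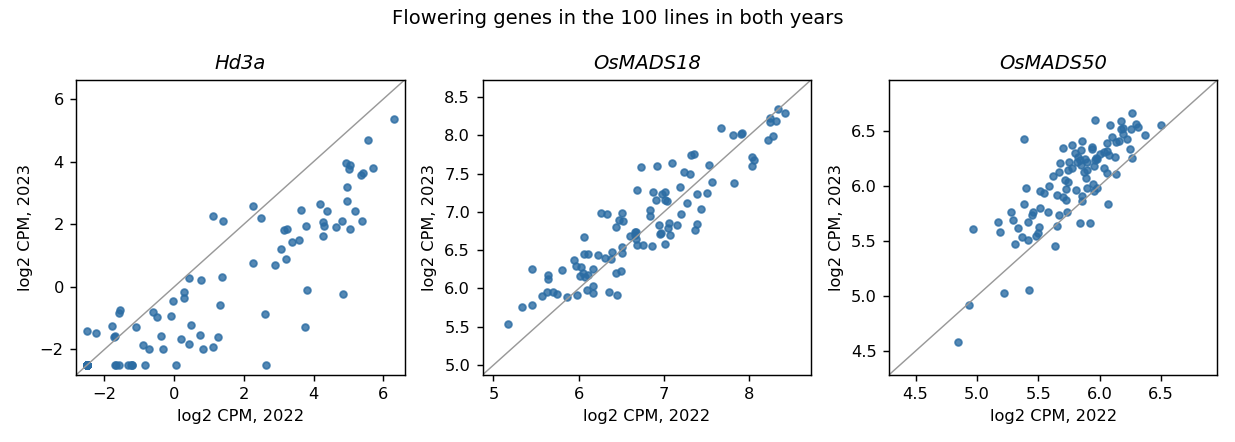
Each point is 1 of the 100 lines, with log2 CPM in 2022 on the x axis and in 2023 on the y axis, for Hd3a, OsMADS18 and OsMADS50, and the diagonal marks equal values. Most lines lie under the diagonal for Hd3a (72 lines higher in 2022), and the points of OsMADS18 lie along it (r = 0.908).

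The third comparison asked whether the florigen gene Hd3a and the floral MADS-box genes moved together across lines within a year. Hd3a rose with OsMADS14, a gene that florigen activates, in both years (r = 0.892 in 2022 and 0.841 in 2023, rho = 0.868 and 0.814). OsMADS15 (Os07g0108900), which had 0 counts in 72 lines in 2022 and 79 in 2023, had a lower r with Hd3a, at 0.649 and 0.520 (rho = 0.705 and 0.518). Permutation p was 1e-05, the smallest possible, for each r and rho (adjusted p = 1.11e-05 for r over the 10 tests run). Hd3a also fell with line number in both years, and OsMADS14 followed column position in both. A trend that the genes share over the lines may therefore raise these values. The permutations do not account for such a trend, and no r of a pair was computed with it removed.

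Hd3a had 0 counts in 24 lines in 2022 and in 33 lines in 2023. Over the lines that read both genes, r of Hd3a with OsMADS14 was 0.844 (67 lines) and 0.724 (60 lines), and with OsMADS15 it was 0.417 (27 lines) and 0.361 (20 lines). Without the 2 farthest lines r over all lines was 0.886 and 0.830 with OsMADS14, and 0.648 and 0.462 with OsMADS15. The lowest r in the 30 lines with the deepest 2022 libraries was 0.386, for OsMADS15 in 2023, where the other 70 lines gave 0.659. The difference of r between the years did not pass for OsMADS14 (0.0508, permutation p = 0.126) or OsMADS15 (0.128, permutation p = 0.0688, adjusted p = 0.158 and 0.115 over the 5 differences tested).

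The fourth comparison asked which genes were read in some lines and silent in others. KSL10 (Os12g0491800), a diterpene synthase of phytoalexin synthesis, was read by 30 lines in 2022 (mean 15.2 CPM) and 23 in 2023 (11.7 CPM), was off in 67 and 70 lines and lay between in 3 and 7. Of 91 lines scored in both years, 87 had the same state. Its off lines held 12 counts in all in 2022 and 11 in 2023. Among genes without a name, Os06g0580100 had a mean of 632 CPM in the lines that read it and was on in 28 and off in 68 lines in 2022, with 5 counts in all in its off lines. Os01g0361000, at 220 CPM, was on in 83 lines and off in 10.

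Of 17681 genes that reached 2 CPM in at least 10 lines in both years, 1.26% were on/off in both years, and a further 16 genes were on/off in 2022 alone and 16 in 2023 alone. Over the genes on/off in both years the state was the same in both years in 99.1% of 21515 scored pairs of gene and line, against a mean of 60.2% and a highest of 61.7% in random pairings of the lines. In 101 genes every scored line had the same state. On/off genes were frequent on chromosome 11, with 49 of 939 such genes (5.22%, odds ratio 5.24, Fisher's exact test two-sided, BH adjusted p = 1.12e-16 over 12 chromosomes), and on chromosome 12, with 26 of 954 (2.73%, adjusted p = 0.000707). They were sparse on chromosome 3 (8 of 2397, 0.334%, adjusted p = 5.5e-06) and chromosome 5 (4 of 1433, adjusted p = 0.00039). The states of neighbouring on/off genes were correlated across lines (median absolute r at least 0.877 up to 20000 locus numbers apart), so these genes were not independent and the p-values are too small. At a threshold of 5 CPM in place of 2 the number in both years was 127.

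**Figure D4:**
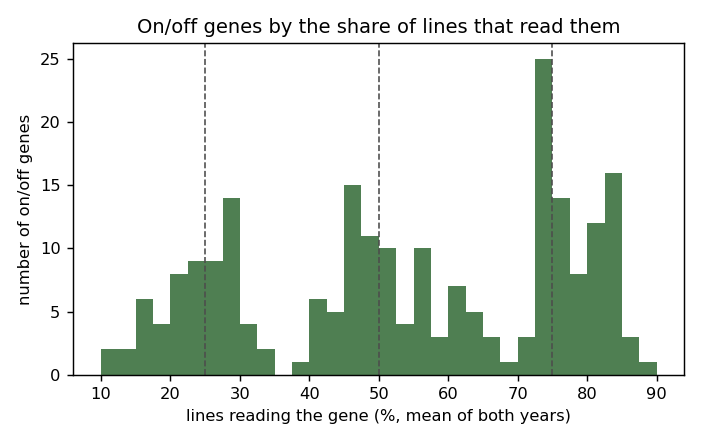
The histogram counts the on/off genes on the y axis by the percent of lines that read them, averaged over both years, on the x axis, with dashed lines at 25, 50 and 75%. It holds the genes on/off in both years, with a median of 54.8% of lines.

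The on/off genes also told the lines apart. Each of the 100 libraries of 2022 was most similar to the 2023 library with its own line number, and the same held for 100 of 100 in the other direction. The lowest r of a line with itself was 0.794 and the highest with another line was 0.641. Over all 10226 genes with a mean of at least 10 CPM, 97 and 96 lines found their own library.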

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

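The splits by the depth of the 2022 library and the removal of a trend over column position were chosen after the data were seen, and the other alternatives were planned. The split by depth also largely parted the lines by number and column position, so in it depth cannot be told apart from these. For the years, 131 genes were called higher in 2023 and 157 higher in 2022. Fitted with the line number as a replicate block these were 128 and 157, with 87.8% of the calls kept, and the block changed the calls of 4 of 67 list members, among them OsMADS18 (0.08). DESeq2 called 134 and 158, RLE size factors 134 and 155, the libraries without the 6 smallest 132 and 157, and the 50 lines with the lower numbers 160 and 111. In both directions together total counts called 332, the 30 lines with the deepest 2022 libraries 356 and the other 70 lines 407. The balance turned between these: 63.5% of the calls were higher in 2023 in the 30 lines, 38.3% in the other 70 and 28.3% by total counts, against 45.5% in all lines. The number moved to 1560 at 1.5-fold and 101 with glmTreat (both follow from the threshold), to 1213 with no filter (34142 genes tested, 62.2% higher in 2023), to 180 with thinned libraries (15365 tested) and to 544 in the 50 lines with the higher numbers, whose cause was not tested.

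Repeatable genes numbered 4111. They were 2420 at a mean of at least 10 CPM, where 10226 genes were tested, and 2669 in the 30 lines with the deepest 2022 libraries, which are fewer lines. The other alternatives gave 3032 (thinned) to 4844 (trend over position removed). On/off genes in both years, 1.26% of those that could be, numbered 127 at 5 CPM, a stricter rule, and 173 to 290 under the other 4 alternatives. The matching of lines gave 96 to 100, and all 4 flowering correlations passed with RLE size factors, a prior count of 0.5 and 5 components removed. Of the lists, 3 passed with RLE size factors and with the replicate block and 2 with an estimated correlation. No list passed for repeatability under either alternative.

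Single genes reversed in a few settings, and the cause was not tested. By total counts OsGI had −0.0236. In the 30 lines with the deepest 2022 libraries GS1;1 had −0.0176, IRO3 −0.0258, PHYC 0.10 and PHYB 0.31, and the r of NAL1 (Os04g0615000) between the years was −0.0351 against 0.348 over all lines. NAS3 had −0.0203 in the 50 lines with the higher numbers. PHYB, which did not pass over all lines, passed upward in the 30 lines and at 0.17 in the 50 with the lower numbers, and downward at −0.22 in the 50 with the higher numbers, −0.18 in the 70 with shallower 2022 libraries and −0.15 by total counts. OsELF3-1, which did not pass over all lines, passed downward under 4 alternatives (−0.0502 to −0.15). PHYC passed in both directions, downward over all lines and upward in the 30. In the 30 lines with the deepest 2022 libraries, which are fewer, the change of SALT was 1.19 against 1.08 over all lines. Those of CKX2, PCNA, OsMADS50, NOL, SE5, Ehd3, NIA1 (0.17 against 0.61) and PT8 were smaller than over all lines. All of these genes kept their direction between the years there and no longer passed. The same held for DTH8 (0.14) and NCED3 (−0.16) in the 50 lines with the higher numbers, DTH8 (0.15) in the 70 lines with shallower 2022 libraries and Ehd4 (0.0352) by total counts. It also held for IRO3 and NAS3 by total counts, OsGI and NAS3 in those 70 lines, OsGI and Hd16 in the 50 lines with the higher numbers, and CKX2, GS1;1, IRO3 and PHYC in the 50 with the lower numbers. Of 45 named genes between the years 24 kept their direction and their side of the threshold throughout. Among the alternative values of all 45, 23 lost the threshold and 8 gained it with the direction kept, and 7 reversed. For the 40 named genes of the repeatability these numbers were 23, 21, 10 and 1. Depth limits genes near 1 CPM, which had about 3 counts in the shallowest library.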

Other observations

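The tests of OsLHY (Os08g0157600) and of the genes with a negative correlation between years, the test of whole chromosomes and the relations with line number were chosen after the results were seen, and the others were planned. OsMADS1 (Os03g0215400), a gene of the floral organs, was read in these leaves at 0 to 27.6 CPM in 2022 and 0 to 30.8 CPM in 2023. It fell with line number in both years (r = −0.696 and −0.663, rho = −0.687 and −0.662, permutation p = 1e-05 each, the smallest possible, −0.692 and −0.660 without the 2 lines of the most extreme numbers). Hd3a (Os06g0157700) did so too (r = −0.715 and −0.621, rho = −0.723 and −0.634, permutation p = 1e-05 each, −0.717 and −0.626 without those 2 lines), and so did OsMADS18 (Os07g0605200) with r = −0.586 and −0.414 (rho = −0.591 and −0.430, permutation p at most 4e-05, −0.577 and −0.406 without those 2 lines). The same pair of lines was the most alike by the on/off genes in both years (r = 0.645 and 0.633).

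The on/off genes were weighed against depth and against inheritance. The number of on/off genes that a library read followed its total count with r = 0.0999 in 2022 and 0.0551 in 2023 (permutation p = 0.324 and 0.588), which argues against depth as the main source. Both predictions of inheritance were met. Of 109 windows along the chromosomes 60.6% held a gene read by about 25, 50 or 75% of the lines (binomial one-sided p = 9.05e-07 against uniform shares). Windows of a chromosome were linked, with a median absolute r of 0.270 between states 20000 to 100000 locus numbers apart in 2022, so this p is too small, and flipping the excess of whole chromosomes gave p = 0.00903 (exact, one-sided, 12 chromosomes). The states of genes up to 20000 locus numbers apart had a median absolute r of at least 0.877, against medians of 0.0749 and 0.0720 for genes on different chromosomes. The pattern may therefore come from segments inherited from the 4 parents. Whether a silent gene is not transcribed, is missing from a parent's genome or differs from the reference so that its reads were not counted stays open, since the reads were not analysed here.

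OsLHY followed the column order of the 2022 table with r = 0.964. Among the 70 shallower libraries r was 0.945, which argues against depth. Its r between the years was 0.0423 (0.170 with the trend over position removed), which argues against an inherited difference as the main source. In the 30 lines with the deepest 2022 libraries it was 0.501. There OsLHY rose with position in 2022 (r = 0.881), and it fell along columns 1 to 50 in 2023 (r = −0.766). With column orders that run in opposite directions such trends can give a positive r, so the 0.501 cannot tell an inherited difference from the column order. OsGI (Os01g0182600), which rises during the day as OsLHY falls, went the other way along the columns (r = −0.652), so the columns may follow the time of collection within the morning, a hypothesis that the labels give no times to test. It rests on OsGI alone, since OsPRR73 (r = 0.481), OsELF3-1 (r = 0.425) and OsPRR95 (r = 0.253) rose along the columns as OsLHY did. Of 18490 genes 9739 followed column position in 2022 and 1655 in 2023.

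The 44 genes with a negative correlation between years had a median r of −0.284. With the trend over column position removed in each year it was −0.0410. The column orders of the years ran in opposite directions (r = −0.788), so trends of the same sign along both tables would give a negative r. Only 2 of the 44 genes had trends of opposite sign along the columns of the 2 tables. The negative values may therefore come from the order of the columns or from whatever it follows. Line number and column position go together (r = −0.743 in 2022 and 0.729 in 2023), so removing the trend also takes out differences between lines that follow their number.

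Neither large count was reached by random labels of the libraries or random pairings of the lines. This does not bear on library sets, the time of collection or the order of the columns, which such labels and pairings break up too. For the years 1 of 41 splits of the libraries, the real one, gave as many genes, with 131 higher in 2023 and 157 higher in 2022 against a highest of 1 in all in the others (20 random splits and 20 swaps of the years within lines). For repeatability 1 of 101 pairings of the lines, the real one, gave as many, with 4111 against a highest of 3.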
